A study of Mus musculus with 8 samples.

How the data were processed

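The samples were 8 dorsal skin samples of female Hos:HR-1 mice, 4 on a control diet and 4 on a diet with collagen hydrolysate, mapped to their groups by the sample titles. Per the labels' protocols, frozen skin was powdered, total RNA was extracted, and 200 ng of it was converted to biotinylated RNA with a kit that copies from the 3' end of transcripts and hybridised to an oligonucleotide array. Whole skin was used, so each value averages epidermis, dermis, any hair follicles and any attached tissue.

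The deposited values are on a log2 scale, 1 column per array, as judged from their range of 5.34 to 14.27. The submitters' processing notes name R 2.7.2, and the summarization and normalization are not given in the sources used here. The quartiles of the 8 arrays differed by at most 0.00138 and differences between arrays were very small: 209 of 45037 probe sets had an SD above 0.01 over the 8 arrays. The direction of a difference and its size relative to the spread between replicates can be read from such values, but the fold change of the RNA cannot. No signal over background came with the values, so precision was judged only by the spread between the arrays of each diet and their number. No 2 arrays shared more than 0.0177% of their values, and each was counted as a sample.

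Of 45101 probe sets, 64 control probe sets were set aside. By the platform annotation, which can be old, 34945 of the others name 1 gene symbol, 932 several and 9160 none. Of the first kind, 34741 had their Entrez ID in the reference gene table, with 0 symbols written differently there. Only probe sets with 1 symbol were used for genes. Each gene was represented by the probe set with the highest mean over all 8 arrays, which gave 18193 genes, and the lowest 30% by mean level were left out, which left 12735. The genome build behind the annotation is not named, so no positions are given.

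The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided) on the deposited values, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 6 residual and 0.61 prior degrees of freedom, so variances were moderated little. A difference in SD units is the fitted difference, collagen minus control diet, divided by the gene's pooled within-group SD. The same fit was run on all 31526 probe sets above the same filter. Before the data were examined, 37 gene lists were fixed (skin pathways and markers of cell types that whole skin can hold), and those with at least 5 members tested were compared with all other genes by camera at its preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The score of a list in an array is the mean over its genes of the deviation from the gene's mean over all arrays in within-group SD units, and scores were compared by an exact permutation test over all 35 splits of 8 arrays into 4 and 4.

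Genes named in the text follow a rule also fixed before the data were examined. For each direction it takes 12 genes with an adjusted p below 0.05 and non-overlapping groups, filled with the non-overlapping genes of the smallest unadjusted p, each said not to pass, where there are fewer. Clones and predicted genes are skipped in these 2 lists. It adds up to 3 members with the smallest p of each list described with its genes, and always *Col1a1*, *Col1a2*, *Col3a1*, *Eln*, *Has2*, *Mmp2*, *Krt5*, *Krt14*, *Krt10*, *Flg*, *Lor* and *Aqp3*.

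The fit was tested on simulated arrays with the real means and SDs of the 12735 genes, in which 200 genes were changed. It called 13.4% of genes changed by 3 within-group SD, 85.1% of those changed by 6 and 100% of those changed by 10, with 0 calls of the wrong sign and 10 calls among unchanged genes. With many genes changed, the adjusted threshold is easier to reach than with few. Simulated sizes also count in the SD used to draw the values, and not in an SD estimated from the arrays. In the real data *Plk1* at -9.83 SD had an adjusted p of 0.0510 in limma, and *Grk6* at -9.63 SD one of 0.278. The simulated shares therefore do not tell which changes would have been found in the real data. A simulated shift of the cell cycle list by 1 SD was called by camera at the preset and at the estimated correlation, with 0 other lists called. The simulated genes varied independently of each other, whereas the estimated correlation within real lists reached 0.82 (skeletal muscle). The 0 other calls therefore do not show how often camera calls unshifted lists of correlated genes.

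Alternatives fixed in advance were no filter or a filter at 50%, quantile normalization, median centring, no intensity trend, robust variances, array weights, the replicate number as a block, the mean of all probe sets of a gene, an adjusted p below 0.10, the other list tests, and leaving out each array in turn. Chosen after seeing the data were a model without moderation, the skeletal muscle score as a covariate, a shift of each array by its median standardized deviation, and leaving out the 2 arrays lowest in skeletal muscle genes. The mice were housed 4 to a cage, and which arrays share a cage is not given in the sources used here.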

Results

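Gene expression was measured on 8 oligonucleotide arrays in dorsal skin of female Hos:HR-1 mice, a hairless laboratory strain. The mice had eaten for 12 weeks either AIN-93G, a purified rodent diet that served as the control, or the same diet with fish-scale collagen hydrolysate, which is collagen cut into peptides, at 2 g for every 100 g of control diet. Feeding began at 9 weeks of age and skin was taken at 21 weeks. The study held 16 mice, 8 on each diet, and the arrays cover 4 mice of each diet, which the labels call biological replicates. The comparison asks which genes of the skin differ in expression between the diets. The number of arrays limits its precision: an exact two-sided permutation test of 4 arrays against 4 cannot give a p below 0.0286. The deposited log2 values lay between 5.34 and 14.27, and they differed very little from array to array. The median SD of a probe set over the 8 arrays was 8.66e-06, and 37 of 45037 probe sets had an SD above 0.1. How the values were summarized and normalized is not given in the sources used here, so a difference on this scale is no fold change of RNA. Differences are therefore given as collagen minus control diet in units of the gene's pooled within-group SD, with the difference on the deposited log2 scale beside some of them.

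No single gene passed the test for a difference between the diets. The gene with the smallest p was *Plk1* (probe set 1448191_at), a kinase that drives mitosis, at -9.83 SD and -6.87e-05 ± 4.97e-06 (SE, n = 4 per diet) on the deposited scale, with an adjusted p of 0.0510 in limma's moderated test. All 4 collagen-diet arrays lay below all 4 control-diet arrays for this gene. Among 12735 genes tested, 0 had an adjusted p below 0.05, and 682 had an unadjusted p below 0.05 where chance alone gives 637. Of these, 528 were lower and 154 higher on the collagen diet. Without moderation of the variances the count at an adjusted p below 0.05 was also 0, with 673 genes at an unadjusted p below 0.05. The groups did not overlap in 421 genes, which is 3.31% of those tested against 2.86% expected by chance, and 322 of the 421 were lower on the collagen diet. Of 31526 probe sets, which include those that name several genes or none, 0 passed as well, 1758 had an unadjusted p below 0.05 and the smallest adjusted p was 0.0656. With genes in the lowest 50% of mean level left out *Plk1* passed (adjusted p = 0.0397 in limma), as it did without control replicate 1 (0.0287).

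The 12 genes ranked first in each direction did not pass the test, and in each of them all 4 arrays of one diet lay on one side of the other 4. Higher values on the collagen diet were led by *Fam221a* (1434428_at, 5.0 SD) and *Tnfrsf11a* (1419214_at, 4.51 SD), which encodes the receptor RANK, neither of them passing, with adjusted p of 0.278 and 0.370. *Ephb1* (1455188_at), an ephrin receptor, differed by 4.53 SD, *Plxna2* (1455037_at), a semaphorin receptor, by 4.40 SD and *Nrip1* (1434384_at), a nuclear receptor corepressor, by 4.10 SD. *Hspa12a* (1434051_s_at) differed by 3.55 SD, *Clip4* (1427278_at) by 3.54 SD, *Coch* (1423285_at) by 3.29 SD, *Ralgps2* (1428789_at) by 3.22 SD and *Lrrc15* (1453214_at) by 3.18 SD. *Krt25* (1418173_at), a keratin of the inner root sheath of the hair follicle, differed by 3.07 SD and *Nectin3* (1448673_at), a cell adhesion molecule, by 2.94 SD. Lower values followed *Plk1* in *Grk6* (1437436_s_at), a kinase of G-protein-coupled receptors, at -9.63 SD, and in *Hira* (1450050_at), a histone chaperone, at -5.81 SD. *Apoe* (1432466_a_at), the lipid carrier apolipoprotein E, differed by -5.49 SD, *Slc25a28* (1424776_a_at), a mitochondrial iron carrier, by -5.45 SD, *Eml2* (1428173_at) by -5.32 SD and *Dohh* (1417322_at), an enzyme of hypusine formation, by -5.29 SD. *Gpx4* (1451695_a_at), which reduces lipid peroxides, differed by -5.13 SD, *Zbtb7a* (1450093_s_at) by -5.05 SD, *Decr2* (1423495_at), a peroxisomal reductase, by -4.83 SD, *Prss12* (1420388_at) by -4.63 SD and *Smco4* (1419403_at) by -4.38 SD. Apart from *Plk1*, the adjusted p of the lower genes lay between 0.278 and 0.370, and that of the higher genes between 0.278 and 0.643. Quantile normalization turned the direction of *Ephb1*, *Ralgps2*, *Plxna2*, *Grk6* and *Prss12*, and median centring that of *Plxna2*. After quantile normalization *Apoe* and *Gpx4* had equal arrays or equal group means, and so no direction.

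**Figure D1:**
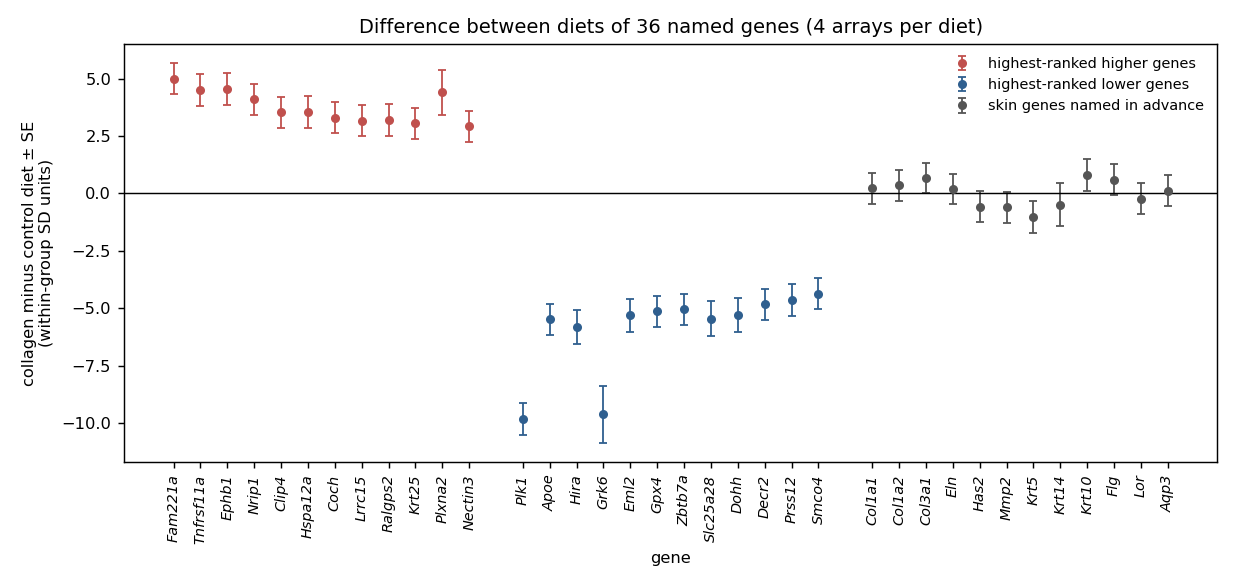
Difference between diets of 36 named genes in within-group SD units (vertical axis), one point per gene (horizontal axis) with its SE, from 4 arrays per diet. *Plk1* lies at -9.83 SD, and the 12 skin genes named in advance lie between -1.02 and 0.80 SD.

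Cell cycle genes were lower as a group in the skin of mice on the collagen diet. Of 27 genes tested in this list, 24 were lower and 3 higher, with a median of -1.77 SD. After *Plk1*, the members with the smallest p were *Cdc20* (1439377_x_at), an activator of the anaphase-promoting complex, at -4.0 SD and *Cdk1* (1448314_at), the kinase of entry into mitosis, at -3.38 SD, and neither passed over all genes. The list passed limma's camera test with an adjusted p of 1.57e-14, and it passed with an adjusted p of 0.0105 with an estimated correlation. At an unadjusted p below 0.05 stood 17 members, all lower, and 9 had an adjusted p below 0.05 adjusted over the list alone, against 0 over all genes tested. The mean score of the list was 0.984 ± 0.451 (SD, n = 4) on the control diet and -0.984 ± 0.650 (SD, n = 4) on the collagen diet, with all 4 collagen-diet arrays below all 4 control-diet arrays (exact permutation p = 0.0286, adjusted p = 0.529 over 37 list scores). As no exact p can lie below 0.0286, this adjusted p could fall below 0.05 only if many lists reached that p. Of 26 further probe sets of these genes, 22 (84.6%) went the same way as the one tested, against 404 of 561 (72.01%) for genes with an unadjusted p below 0.05 and 58.8% over all genes. Markers of basal keratinocytes, the layer that holds the dividing cells of the epidermis, had a median of -0.05 SD over 14 genes (adjusted p = 0.928). Quantile normalization ended the call of the cell cycle list (adjusted p = 0.301), and fry, which does not compare the list with other genes, gave an adjusted p of 0.200.

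**Figure D2:**
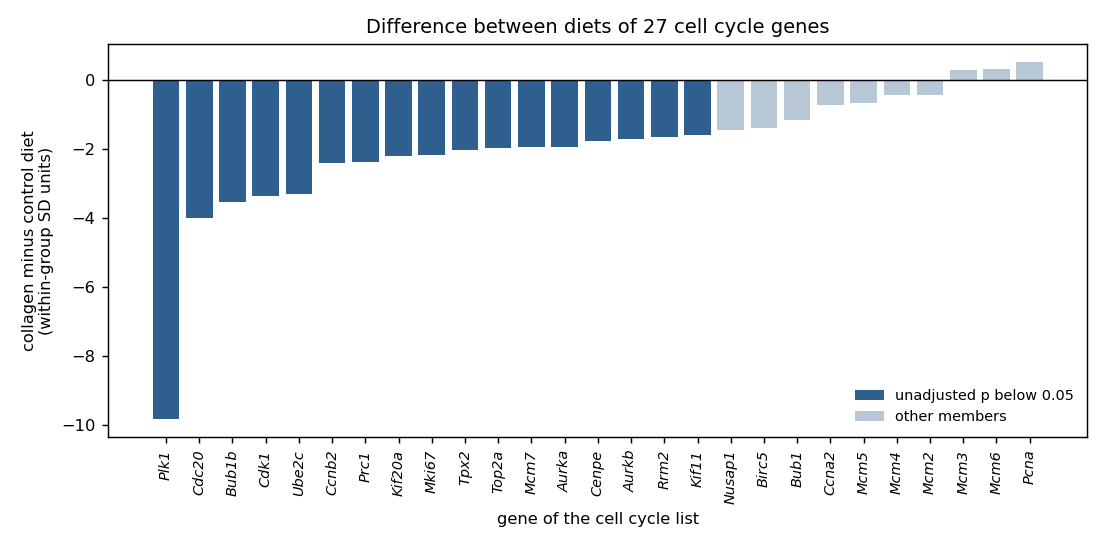
Difference between diets of the 27 cell cycle genes tested (horizontal axis), as collagen minus control diet in within-group SD units (vertical axis), from 4 arrays per diet. Bars start at 0, and the 17 dark bars, all negative, mark an unadjusted p below 0.05. The median of the list was negative under quantile normalization (-0.22 SD, 20 of 27 lower) and median centring (-0.52 SD, 26 of 27 lower). Over all genes tested 65.7% and 86.5% were lower in these settings, so a negative median there says little by itself.

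Genes of the hair shaft and follicle were higher as a group on the collagen diet in camera with its preset correlation, and did not pass with an estimated one. In the list of hair keratins and follicle differentiation 28 of 32 genes were higher, with a median of 1.16 SD and an adjusted p in camera of 3.90e-11, against an adjusted p of 0.164 with an estimated correlation. After quantile normalization 19 of 32 were higher with a median of 0.12 SD. After median centring 22 were higher with a median of 0.32 SD. *Krt25* and *Krt73* (1436557_at), both keratins of the inner root sheath, differed by 3.07 and 2.64 SD, while *Hoxc13* (1425874_at), a transcription factor of hair keratin genes, went the other way at -2.12 SD. Keratin-associated proteins, which embed the keratin filaments of the hair shaft, were higher in 14 of 14 genes tested, with a median of 1.14 SD and an adjusted p in camera of 1.07e-08, against an adjusted p of 0.262 with an estimated correlation. Their median was 0.52 SD after quantile normalization and 0.77 SD after median centring. *Krtap8-1* (1427211_at) differed by 2.12 SD, *Krtap13-1* (1428007_at) by 2.05 SD and *Krtap22-2* (1458467_at) by 1.85 SD. At an unadjusted p below 0.05 stood 8 higher genes and 1 lower gene of the first list and 5 higher genes of the second, and 0 passed adjusted over the list alone in either. Of 11 further probe sets of these genes 4 (36.4%) went the same way as the one tested, against 72.01% for genes with an unadjusted p below 0.05 and 58.8% over all genes.

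The cornified envelope list, which holds proteins of the outermost epidermis, was higher in 43 of 54 genes with a median of 0.31 SD (adjusted p = 0.000970, and adjusted p = 0.873 with an estimated correlation). After quantile normalization 39 of 54 were higher with a median of 0.49 SD. After median centring 28 were higher and 26 lower, with a median of 0.02 SD. Its members with the smallest p were *Tchh* (1434425_at), trichohyalin of the inner root sheath, at 2.01 SD, *Lce3b* (1429641_x_at) at 1.66 SD and *Krt77* (1433923_at) at 1.64 SD. Cholesterol synthesis genes were lower in 15 of 20 with a median of -0.87 SD (adjusted p = 0.0105, and adjusted p = 0.262 with an estimated correlation), and the median was -0.39 SD after quantile normalization and -0.24 SD after median centring. Over all genes tested 65.7% and 86.5% were lower in these 2 settings. The cholesterol synthesis genes were led by *Hmgcs1* (1433443_a_at), which makes the precursor of mevalonate, at -2.86 SD, *Lss* (1420013_s_at), lanosterol synthase, at -2.04 SD and *Mvd* (1417303_at), mevalonate diphosphate decarboxylase, at -1.88 SD. Genes of the circadian clock were higher in 11 of 15 with a median of 0.54 SD (adjusted p = 0.0493, and adjusted p = 0.262 with an estimated correlation), and in 8 of 15 after either normalization, with medians of 0.13 and 0.11 SD. They were led by *Per3* (1421087_at) at 1.63 SD, *Per2* (1457350_at) at 1.30 SD and *Nr1d2* (1416958_at) at 1.15 SD. At an unadjusted p below 0.05 stood 3 higher cornified envelope genes, 3 lower cholesterol synthesis genes and 1 higher clock gene, and 0 passed adjusted over the list alone in each. Leaving out a single array ended the call of each: control replicate 3 or collagen replicate 1 for the cornified envelope (adjusted p = 0.532 and 0.0860), control replicate 1 or collagen replicate 3 for cholesterol synthesis (0.248 and 0.0907), and control replicates 1 or 3 or collagen replicates 3 or 4 for the clock (0.248, 0.0748, 0.172 and 0.152).

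**Figure D3:**
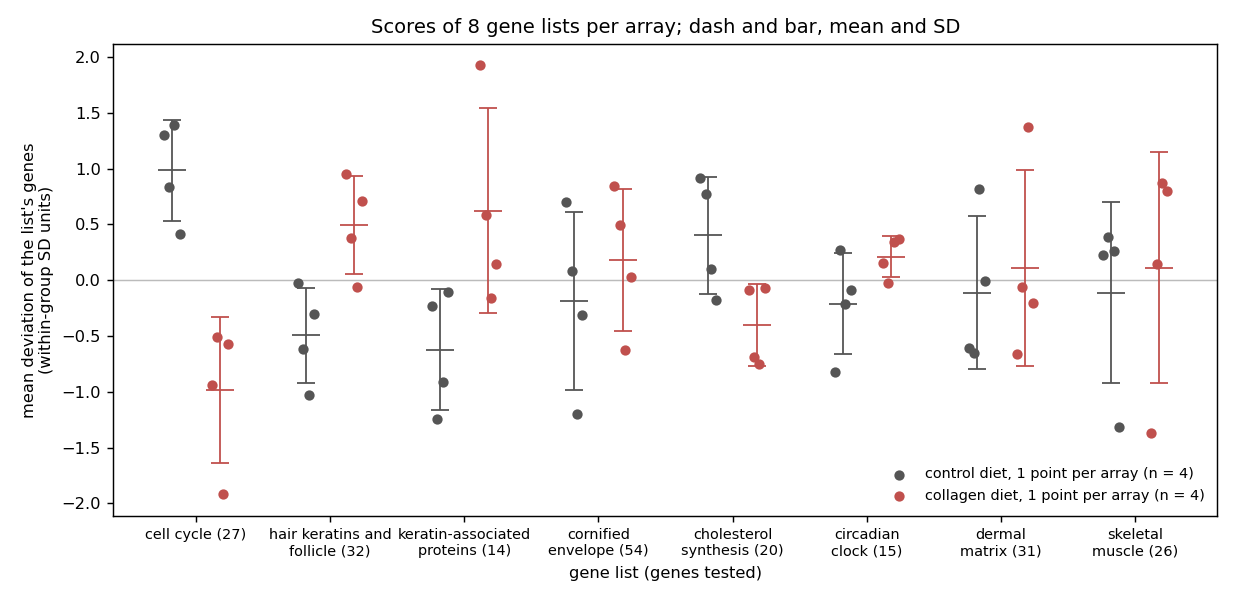
Score of 8 gene lists in each array, the mean deviation of the list's genes in within-group SD units (vertical axis), with 1 point per array, a dash for the mean of 4 arrays and a bar for the SD. The cell cycle scores of the 4 collagen-diet arrays lie below those of the 4 control-diet arrays, and 1 array of each diet is low in skeletal muscle genes (-1.32 and -1.37).

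Genes of the dermal matrix, which include those of the skin's own collagens, did not pass as a list. Of 31 genes of fibrillar collagens and dermal matrix proteins 18 were higher and 13 lower, with a median of 0.20 SD (adjusted p = 0.108). The list passed as higher after median centring (adjusted p = 6.81e-05), without control replicate 3 (0.000103), without collagen replicate 1 (0.000370) or 4 (0.0481) and without the 2 arrays low in skeletal muscle genes (0.000860). Higher here means relative to all other genes, in camera with its preset correlation. After median centring 16 of the 31 genes were lower, with a median of -0.04 SD, while 86.5% of all genes tested were lower. With all 8 arrays as deposited and an estimated correlation, which was 0.48, the list gave an adjusted p of 0.879 in camera. *Col1a1* (1423669_at) differed by 0.23 SD, *Col1a2* (1450857_a_at) by 0.36 SD and *Col3a1* (1427883_a_at) by 0.67 SD, which are the chains of collagen types I and III, and *Eln* (1420855_at), elastin, by 0.20 SD, each with overlapping groups and an adjusted p of 0.999. The member with the smallest p was *Tnc* (1416342_at), tenascin C, at 2.28 SD (adjusted p = 0.799), followed by *Fmod* (1415939_at) at 1.09 SD and *Tnxb* (1450798_at) at -0.96 SD. Enzymes of collagen processing and crosslinking were split evenly, with 12 genes higher and 12 lower (adjusted p = 0.592). Among them *Plod2* (1416686_at), a lysyl hydroxylase, differed by 1.35 SD, *Serpinh1* (1450843_a_at), the collagen chaperone HSP47, by 1.19 SD and *Sec23a* (1423347_at) by 1.05 SD. Matrix proteases and their inhibitors were lower in 13 and higher in 7 genes (adjusted p = 0.592), with *Mmp9* (1416298_at) at 1.76 SD, *Mmp12* (1449153_at) at 1.57 SD, *Ctss* (1448591_at) at 0.94 SD and *Mmp2* (1439364_a_at), gelatinase A, at -0.59 SD. Without collagen replicate 3 the differences of *Col1a1*, *Col1a2* and *Eln* were -0.41, -0.17 and -0.57 SD.

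Basal keratinocyte, water, hyaluronan, barrier lipid, sebaceous and junction lists did not pass either, and 2 of them passed in other settings. *Krt5* (1424096_at) and *Krt14* (1423935_x_at), the keratins of basal cells, differed by -1.02 and -0.48 SD, and of the cornified envelope list *Krt10* (1452166_a_at) of the layers above differed by 0.80 SD, *Flg* (1427268_at), filaggrin, by 0.60 SD and *Lor* (1448745_s_at), loricrin, by -0.23 SD. *Aqp3* (1450460_at), the water and glycerol channel of keratinocytes, differed by 0.13 SD and *Has2* (1449169_at), a hyaluronan synthase, by -0.58 SD, and each of these 7 genes had an adjusted p of 0.999. The list of water channels and natural moisturising factor had 9 genes higher and 8 lower (adjusted p = 0.918), with *Car12* (1428485_at), a carbonic anhydrase, at -2.82 SD, *Padi1* (1419323_at), which citrullinates filaggrin, at 2.50 SD and *Padi4* (1422760_at) at -1.06 SD. In hyaluronan and proteoglycan metabolism 8 genes were higher and 9 lower (adjusted p = 0.726), with *Hmmr* (1425815_a_at), a hyaluronan receptor that also binds the mitotic spindle, at -2.67 SD, *Cemip2* (1451458_at) at 1.92 SD and *Cd44* (1423760_at) at 1.11 SD. Barrier lipid synthesis had 11 genes higher and 17 lower (adjusted p = 0.618), with *Cers4* (1417780_at), a ceramide synthase, at -1.86 SD, *Slc27a4* (1424441_at), a fatty acid transporter, at -1.72 SD and *Fa2h* (1426960_a_at) at -1.49 SD. The sebaceous gland list gave an adjusted p of 0.487, and passed as lower after median centring (3.76e-05), without control replicate 4 (0.0149) and without the 2 arrays low in skeletal muscle genes (0.0160). In it *Cidea* (1417956_at), a lipid droplet protein, stood at -3.59 SD and was the 1 gene below 0.05 adjusted over the list alone, with *Elovl3* (1420722_at) at -2.35 SD and *Dgat1* (1418295_s_at) at -1.99 SD. Tight junction and desmosome genes were lower in 19 of 28 (adjusted p = 0.592, and adjusted p = 0.0146 without collagen replicate 1). *Pkp3* (1418831_at), plakophilin 3, stood at -3.96 SD and was the 1 gene below 0.05 adjusted over this list alone, while *Dsp* (1435494_s_at), desmoplakin, differed by 1.82 SD and *Nectin4* (1451690_a_at) by -1.18 SD.

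No list of markers of other cell types passed the test on the values as deposited with all 8 arrays. Skeletal muscle genes had a median of 0.24 SD (adjusted p = 0.108), and their scores were -1.32 in control replicate 4 and -1.37 in collagen replicate 1 against 0.15 to 0.87 in the other 6 arrays. The list passed as higher after quantile normalization (adjusted p = 2.90e-06), after median centring (1.50e-10), without those 2 arrays (2.34e-06), without control replicate 1 (0.0261), 2 (0.0131) or 3 (0.0263) and without collagen replicate 1 (5.64e-09). Mast cells and granulocytes had a median of 0.29 SD over 12 genes (adjusted p = 0.108), smooth muscle 0.22 SD over 9 (0.286), Schwann cells and melanocytes 0.33 SD over 12 (0.286) and T and NK cells -0.40 SD over 12 (0.325). Mast cells and granulocytes passed as higher after quantile normalization (adjusted p = 0.00263), after median centring (1.12e-06), without control replicate 4 (6.86e-06), without collagen replicate 2 (0.0444) and without the 2 arrays low in skeletal muscle genes (0.000117). Those 2 arrays left out, smooth muscle passed as higher (adjusted p = 0.0373) and T and NK cells as lower (0.0429, and 0.0342 without collagen replicate 1), while Schwann cells and melanocytes passed as higher after quantile normalization (0.0287). Endothelium and pericytes had a median of 0.09 SD (0.609), adipocytes 0.12 SD (0.650), fibroblasts 0.20 SD (0.778), macrophages and dendritic cells 0.20 SD (0.876) and B cells and plasma cells 0.03 SD (0.918). Erythrocyte genes, with 3 members tested, were too few for the test. Among the remaining pathways the median was -0.38 SD for NRF2 antioxidant genes (0.128), -0.42 SD for immediate early and heat shock genes (0.132), 0.13 SD for peptide and amino acid handling (0.135) and 0.23 SD for mitochondrial respiration (0.135). NRF2 genes passed as lower without control replicate 2 (adjusted p = 0.0392), without collagen replicate 4 (0.0492) and after median centring (0.0288). Immediate early genes passed as lower without control replicate 1 (adjusted p = 0.0239) or 2 (0.00662), without collagen replicate 1 (0.0244) and after median centring (0.000341). Peptide handling passed as higher without control replicate 4 (adjusted p = 0.0382) and without the 2 arrays low in muscle genes (0.0446). Mitochondrial respiration passed as higher without control replicate 2 (adjusted p = 0.0132), without collagen replicate 1 (2.12e-06), without those 2 arrays (0.00373) and after median centring (0.0288). In the last setting it was higher only relative to other genes, with 17 of 28 genes lower and a median of -0.09 SD. On the values as deposited the median was 0.09 SD for the basement membrane (0.211), -0.45 SD for TGF-beta signalling (0.233), 0.13 SD for the interferon response (0.286) and 0.06 SD for inflammatory cytokines (0.381). The basement membrane passed as higher without control replicate 3 (adjusted p = 0.0263) or 4 (0.0114) and without the 2 arrays low in muscle genes (0.0160), and TGF-beta signalling as lower after median centring (0.00611). The interferon response passed as higher without control replicate 3 (adjusted p = 7.85e-06), without collagen replicate 1 (0.0177), after quantile normalization (0.0285) and after median centring (0.00777). Inflammatory cytokines passed as higher without control replicate 4 (adjusted p = 3.72e-05), without the 2 arrays low in muscle genes (0.000116) and after median centring (0.0108). In the last setting they too were higher only relative to other genes, with 11 of 21 lower and a median of -0.04 SD. As deposited, the median was 0.01 SD for the unfolded protein response (0.544), 0.05 SD for wound keratins and alarmins (0.903) and -0.22 SD for cytosolic ribosomal proteins (0.999). In 11 of 36 lists, none of them past the threshold, the median or mean differed in sign from the camera test. Altogether 6 of 36 lists passed camera, 4 higher and 2 lower, against 1 with an estimated correlation and 0 in fry. The number passing was 16 after median centring, 15 without the 2 arrays low in skeletal muscle genes, and 10, 11 and 12 without control replicate 2, control replicate 4 and collagen replicate 1. At the preset correlation 29 of the 35 splits of the 8 arrays into 4 and 4 gave at least 6 lists. The median over the splits other than the real one was 10, so a count of 6 is no sign of a diet effect.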

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

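The count of skeletal muscle genes that are lowest in 2 arrays was chosen only after that pattern was seen. In each group of 4 arrays the gap of the highest or lowest array to its neighbour was set against the group's range, over 224 groups (named genes and list scores), and 11 stood apart where chance gives about 1 in 20, or 11.2.

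On the control diet, replicate 1 was the highest for *Krt25* (gap over range 0.887) and the lowest for *Mmp2* (0.844), replicate 2 the highest for *Slc27a4* (0.868), replicate 3 the lowest for *Dsp* (0.854) and replicate 4 the highest for *Mmp9* (0.851). On the collagen diet, replicate 4 was the highest for *Nectin3* (0.885) and for *Gpx4* (0.952), replicate 2 the lowest for *Mmp9* (0.942), and replicate 3 the lowest for *Tchh* (0.905) and for the score of wound keratins and alarmins (0.839). Among 5364 probe sets that name no single gene, 1457577_at was lower on the collagen diet, at -8.12 within-group SD, with an adjusted p of 0.0420 in limma over these probe sets and an adjusted p of 0.0913 over all 31526.

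The skeletal muscle score of control replicate 4 lay far below the other 3 control arrays (gap over range 0.901), at -1.32, and collagen replicate 1 lay at -1.37. Of 26 skeletal muscle genes 23 had these 2 arrays as their lowest, against 3 of 9 smooth muscle genes. A pair of arrays drawn at random would be lowest in 3.57%. The 2 arrays were picked by the score of these same 26 genes, so that value does not measure chance for them. Different amounts of skeletal muscle in the skin samples would go with these counts. Poorer RNA or labelling in these 2 arrays stays open, since both lay outside the other 6 in 1 of 5 control probe measures. With 1 such array on each diet the score did not separate the diets (exact permutation p = 0.657), and no biological explanation was tested.

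Chance cannot be excluded for the counts of genes and probe sets: 14 of the 35 splits of the 8 arrays into 4 and 4 gave at least 682 genes at an unadjusted p below 0.05, with a highest other count of 1331, and 10 gave at least 1758 probe sets, with a highest other count of 3456. Genes past an adjusted p of 0.05 appeared in 2 of the other splits, with at most 2 genes. Nor can it be excluded for the number of lists, since 29 of 35 splits gave at least 6, up to 22, and the median of the other splits was 10. With an estimated correlation 1 list passed in the real split and 0 in each of the others. For single lists, 1 of 35 splits, the real one, gave a camera p as small as that of the cell cycle list (4.35e-16, smallest other 1.85e-12). The same held for the hair keratin list (1 of 35, 2.17e-12 against 3.98e-10) and the keratin-associated proteins (1 of 35, 8.88e-10 against 2.05e-08). A share of 1 of 35 is the smallest that this test can give. Only lists that passed camera in the real split were put to it, with no correction for 36 lists. It therefore does not exclude chance for these 3 lists. With an estimated correlation 1, 2 and 1 of 35 splits gave as small a p. The scores of the hair keratin list and the keratin-associated proteins gave an exact permutation p of 0.0571 each, and over 37 list scores the adjusted p was 0.529 for all 3. As no exact p can lie below 0.0286, such an adjusted p falls below 0.05 only if many lists reach that p. The value of 0.529 therefore says little either way. Chance cannot be excluded for the cornified envelope (15 splits with a p as small as 0.000108, smallest other 2.90e-20), cholesterol synthesis (4 splits, 0.00145 against 6.26e-05) or the clock (3 splits, 0.00821 against 0.000821).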

How the results depend on the processing

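Of the alternatives, 4 were chosen after seeing the data: the model without moderation, the skeletal muscle covariate, the shift by the median standardized deviation and leaving out the 2 arrays low in muscle genes. The count of genes was 0 in each setting except the lowest 50% left out (1) and an adjusted p below 0.10 (1), and it ranged from 0 to 1 when single arrays were left out (1 without control replicate 1). The count of probe sets was 1 under quantile normalization, 1 under median centring and 3 at an adjusted p below 0.10, and it ranged from 0 to 1 over single arrays left out (1 without collagen replicate 1). The count of lists was 16 under median centring, 1 with an estimated correlation, 0 in fry and 15 without the 2 arrays low in muscle genes, and ranged from 4 to 12 over single arrays left out (10 without control replicate 2, 11 without control replicate 4, 12 without collagen replicate 1). The 682 genes at an unadjusted p became 73 under quantile normalization and 78 under median centring. Both add shifts larger than most genes' spread: the median within-group SD is 1.94e-05 as deposited, 0.000439 after quantile normalization and 0.000159 after median centring. Quantile normalization left 16 of 76 named genes with equal arrays or equal group means (to within 1e-09), for which it gives no direction. They were *Apoe*, *Gpx4*, *Col1a2*, *Col3a1*, *Mmp2*, *Krt5*, *Krt14*, *Krt10*, *Flg*, *Lor*, *Cers4*, *Hmgcs1*, *Krt77*, *Cidea*, *Pkp3* and *Dsp*.

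Adjusted p of the cell cycle list was 0.301 under quantile normalization and 0.200 in fry, and from 2.60e-16 to 1.03e-09 over single arrays left out. The hair keratin list gave 0.164 with an estimated correlation and 0.375 in fry (single arrays 1.93e-12 to 3.55e-07), and the keratin-associated proteins 0.262 and 0.677 (1.89e-09 to 1.62e-05), with too few members left at the 50% filter. The cornified envelope gave 0.873, 0.981 and, without the 2 arrays low in muscle genes, 0.228 (2.37e-10 to 0.532; 0.532 without control replicate 3 and 0.0860 without collagen replicate 1). Cholesterol synthesis gave 0.154 under quantile normalization, 0.131 for the mean of all probe sets, 0.262 with an estimated correlation and 0.677 in fry (0.000652 to 0.248; 0.248 without control replicate 1 and 0.0907 without collagen replicate 3). The clock gave 0.156 without a filter, 0.228 under quantile normalization, 0.0716 for the mean of all probe sets, 0.262 with an estimated correlation, 0.895 in fry, 0.0673 without moderation and 0.0869 with the muscle covariate (0.000684 to 0.248; 0.248 and 0.0748 without control replicates 1 and 3, 0.172 and 0.152 without collagen replicates 3 and 4). Directions of these 6 lists held in every setting run. Why a list lost its call in a setting was not tested. The values carry no measure of signal over background, so what it limits was not assessed.

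Replicate numbers are shared by the diets without pairing the mice: same-numbered arrays correlated at 0.00448, -0.0184, 0.185 and -0.0717, and 1 of 4 correlated best with its own number. With the replicate number as a block 0 genes, 0 probe sets and 6 lists passed: 5 of those that passed without it and the dermal matrix list (adjusted p = 0.0209), while the clock gave an adjusted p of 0.137. Altogether 16 lists that did not pass did so in 1 or more other settings, among them skeletal muscle in 7, the dermal matrix in 6 and mast cells in 5.

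Of 76 named genes the direction turned under quantile normalization for *Padi1* (-0.0277 SD), *Fmod* (-0.0661), *Plxna2* (-0.0847), *Sec23a* (-0.179), *Per2* (-0.216), *Mmp9* (-0.231), *Lce3b* (-0.280), *Aqp3* (-0.360), *Ralgps2* (-0.398), *Nr1d2* (-0.518), *Ephb1* (-0.576), *Ctss* (-0.707), *Has2* (0.0798), *Prss12* (0.176) and *Grk6* (0.189). Under median centring it turned for *Per2* (-0.0183), *Padi1* (-0.0364), *Plxna2* (-0.0683), *Dsp* (-0.0835) and *Krt10* (-0.135), with array weights for *Eln* (-0.0449) and for the mean of all probe sets for *Krt14* (0.151). Leaving out single arrays turned *Col1a1* (-0.405 to 0.693), *Col1a2* (-0.174 to 0.838), *Eln* (-0.570 to 0.631), *Lor* (-1.08 to 0.177) and *Aqp3* (-0.260 to 1.30).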

Other observations

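Tests chosen only after their results were seen are the comparison of mitotic with replication genes, the hair lists with single arrays left out and the further probe sets of hair genes. Mitotic genes outside the fixed lists were lower on the collagen diet too. Of 61 such genes, chosen as mitotic by textbook knowledge before their values were seen, 55 were lower, with a median of -1.18 SD, and 17 had an unadjusted p below 0.05, each of them lower. Their mean score lay between -0.14 and 0.92 in the control arrays and between -1.15 and -0.24 in the collagen arrays, without overlap. For these genes camera with an estimated correlation gave p = 0.000656 and fry p = 0.0188. Within the cell cycle list, 19 mitotic genes had a median of -2.03 SD with all 19 lower, and 8 genes of DNA replication a median of -0.45 SD with 5 lower.

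*Myh2*, a myosin of fast muscle fibres, had the largest SD over the 8 arrays of all genes tested (0.490), at 7.86 in collagen replicate 1 and 9.25 in collagen replicate 3. *H2-Eb1*, an MHC class II chain of antigen-presenting cells, came next (0.414), at 7.98 in control replicate 2 and between 9.02 and 9.24 in the other 7 arrays. Of 4 probe sets of *H2-Aa*, another class II chain, 3 were lowest in control replicate 2, while 1 probe set of it and those of *H2-Ab1* and *Cd74* had this array within the range of the other 7. These genes were chosen after their values were seen.

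A hypothesis is that fewer skin cells were in mitosis on the collagen diet, a shift of mitotic genes in general and not of the members chosen. The further mitotic genes were mostly lower too, so the shift was not limited to the members chosen. Their mean score gave an exact permutation p of 0.0286, the smallest that 4 arrays against 4 can give. The cell cycle list had already separated the diets on these same arrays. The p of the further genes is therefore no independent sign of fewer cells in mitosis, and does not bear on chance or cage. The difference between mitotic and replication genes (-2.07 SD in their scores, exact permutation p = 0.0286) was noticed in these same genes first, so that its p decides nothing about a larger shift of mitotic genes. A lower share of basal keratinocytes and different amounts of skeletal muscle were not decided by covariate fits. The basal keratinocyte score differed by -0.104 SD between the diets (exact permutation p = 0.886) and the skeletal muscle score by 0.223 SD (0.657). Covariates that differ so little could hardly shrink the shift. With the basal keratinocyte score as a covariate the list kept a median of -1.80 SD and passed camera with an estimated correlation (adjusted p = 0.0338). With the skeletal muscle score the list had a median of -1.76 SD (adjusted p = 0.0432). The authors' normalization stays open, because its method is not given here and quantile normalization ended the call (adjusted p = 0.301) while the list passed after median centring (1.09e-06) and after a shift of each array by its median standardized deviation (1.36e-14). Cage, which cannot be assigned to arrays here, also stays open beside diet.

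A second hypothesis is a different state of the hair follicles, since 28 of 32 hair genes were higher on the collagen diet. The strain is hairless, and the values do not show which follicle structures its skin held. The hair keratin score differed by 0.991 SD between the diets with all 8 arrays. It differed by at least 0.814 SD (without control replicate 3) when 1 was left out, so no single array carried the whole difference. The 95% t intervals lay above 0, the nearest being 0.010 to 1.828 without collagen replicate 4. This check was chosen after its result was seen, on a list that had passed in these same arrays, so it does not bear on chance. More differentiated epidermis was not decided by a covariate fit. The cornified envelope score itself differed by 0.367 SD between the diets (exact permutation p = 0.514), so it could take up little of the difference. Its list also holds *Tchh* of the inner root sheath. With this score as a covariate the hair keratin score differed by 0.806 SD (95% t interval 0.316 to 1.295), and the hair keratin list passed camera with its preset correlation (adjusted p = 9.12e-08). For the keratin-associated proteins a single array stays open, since their difference went from 1.247 to 0.813 SD without collagen replicate 1 and the t interval reached below 0 (-0.137 to 1.763), as it did with all 8 arrays (-0.060 to 2.554). Probe sets that do not measure the transcript stay open and go with the values: 36.4% of 11 further probe sets went the same way, and the exact binomial 95% interval of 10.9% to 69.2% lies below the 72.01% of genes with an unadjusted p below 0.05, though it holds the 58.8% over all genes. The score of the list did not separate the diets at 0.05 (exact permutation p = 0.0571), and both hair lists lost their calls with an estimated correlation.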
